A study of Mus musculus with 10 samples.

How the data were processed

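PyMT-BO1-GFP-Luc cells, a mouse mammary tumor line that carries green fluorescent protein and luciferase, were placed in the mammary fat pad of wild-type (WT) mice and of b3KOM mice, in which integrin beta3 is deleted in cells of the macrophage lineage. The labels state that 100000 cells were given and that tumors were taken on day 10. Per the labels' protocols, cells were separated by fluorescence-activated sorting into tumor cells and CD206hi tumor-associated macrophages (TAMs), 50 ng of RNA was amplified, and Affymetrix arrays were hybridised. Each of the 10 arrays belongs to 1 of 4 groups by its title, with 3 arrays of WT TAMs, 3 of b3KOM TAMs, 2 of tumor cells from WT hosts and 2 of tumor cells from b3KOM hosts. The labels do not say how many mice stand behind an array, so each p-value measures the spread between these samples, which may in part be technical.

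The authors deposited log2 values made with RMA (background correction, quantile normalization and summarisation to 1 value per probeset) in Affymetrix Expression Console, per the submitters' processing notes. The tool versions and the array model are not given in the sources used here. The value table holds 35556 probesets on 10 arrays, with array medians from 4.13 to 4.22 on the log2 scale and no mark for control probesets. The authors also deposited tables of selected genes for the TAMs (122 rows) and for the tumor cells (130 rows). Their titles call them unique differentially expressed genes, though 1 probeset, that of Zfp248, is in both. Per the file headers, each row gives a log fold change of WT against b3KOM, a mean expression value, a statistic t (a score) and a p-value. They are read here as log2 values, a moderated t and an unadjusted p. The largest p-value in either table is 0.00996. In every row the sign of the deposited log2 fold change was that of WT minus b3KOM in the deposited array values. All differences computed here run the other way, b3KOM minus WT. The differences computed from the arrays departed from the deposited ones by a median of 0.0102 in the tumor cell table and 0.0668 in the TAM table, and the deposited mean log2 values departed by up to 0.13 and 0.63, so the TAM table seems to rest on values processed in another way.

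A table that names all probesets was not used here. Probesets were named only from the authors' deposited tables, which cover 251 probesets, and 118 of the 122 TAM genes and 122 of the 130 tumor cell genes matched 1 current RefSeq symbol (assembly GRCm38.p6, used for symbols and for shared chromosomes only). The design written before the data were examined had planned 1 probeset per gene, with every probeset tested if no names were given, and the latter was done. Itgb3, the deleted gene, is not among the named probesets and is not analysed here, so the arrays give no check of the deletion.

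Values were fitted with limma 3.58.1 (lmFit and eBayes, with statmod 1.5.0) in R 4.3.3. A model with 1 mean for each of the 4 groups, with 6 residual and 2.35 prior degrees of freedom, was fitted to the 20246 probesets that exceeded the median of the value table (4.19 on the log2 scale) on at least 2 arrays. Contrasts were b3KOM minus WT in TAMs, b3KOM minus WT in tumor cells, the difference between those (the interaction) and TAMs minus tumor cells. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and an adjusted p under 0.05 counted as a call. Gene lists were fixed before the data were examined, 39 in number. Because names come only from the authors' tables, 4 of them had at least 5 named and tested members, the interferon gamma response, MHC class II presentation, macrophage marker and chemokine lists, all through the tumor cell table. They were tested in the TAM comparison with camera (preset correlation of 0.01), camera with an estimated correlation and fry. In the tumor cell comparison these members had been chosen by the authors on the same arrays, so only counts and medians are given there. Nlrc5, a 10th named member of the interferon gamma list, was named through the TAM table and is not counted in the list, since it was chosen on the TAM arrays. TAM-enriched probesets were defined as those over 4 log2 units brighter in TAMs than in tumor cells (337 probesets), a contrast that is statistically independent of the genotype contrasts.

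Genes are named by a rule written before the data were examined. For each genotype comparison it takes up to 12 named genes per direction whose arrays do not overlap between genotypes, first those past the threshold by size and then those with a change of at least 1.5-fold by unadjusted p. It adds up to 4 members of each gene list by smallest p, the 10 largest per direction between cell types, and 5 per direction for the interaction and for each of the authors' tables. Predicted genes, clone names, small RNAs (microRNAs among them), olfactory and vomeronasal receptors, immunoglobulin and T cell receptor segments, and probesets with several genes were left out by the rule, and any other gene named was chosen after its values were seen. Some genes that the rule takes are not given in the text or the plots.

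The fit was tested on simulated data made from the real means and spreads, with 200 of 20246 probesets changed. Each probeset had independent noise with 1 spread, shared by both cell types. In the TAM comparison it called 32.8% of changes of 1.5-fold, 69.6% of changes of 2-fold and 91.8% of changes of 4-fold. For the tumor cell comparison the corresponding values were 15.8%, 51.6% and 85.8%. False calls made up 6.38% of TAM calls and 4.68% of tumor cell calls. Real TAM arrays vary more than tumor cell arrays, so these percentages do not measure how the fit does on the real arrays. A simulated admixture of 1% TAM signal in b3KOM tumor cell arrays was read back as 0.993% over the 337 TAM-enriched probesets. Of these, 95.3% were higher with 1% added and 50.1% with 0% added, against 83.7% on the real arrays. Alternatives covered no filter, a stricter filter, quantile normalization within each cell type, cyclic loess, an intensity trend with robust fitting, array weights, fits on 1 cell type alone, other thresholds and leaving out each array. Tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. The number of arrays limits the precision of every value.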

Results

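The data are expression values on 10 arrays, from CD206hi TAMs (3 WT and 3 b3KOM) and from tumor cells sorted out of the same kind of day 10 mammary fat pad tumors (2 from WT hosts and 2 from b3KOM hosts). CD206 is the mannose receptor, a surface protein often used to mark macrophages of the alternatively activated kind. Arrays of the same cell type correlated with Pearson's r of 0.981 to 0.985 across probesets in TAMs and 0.990 to 0.993 in tumor cells, and arrays of different cell types with 0.909 to 0.923. Between TAMs and tumor cells, limma called 13383 of 20246 probesets, 5050 higher in TAMs and 8333 lower. With cyclic loess scaling the split was 6763 higher and 6283 lower, so the balance of directions depends on scaling.

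The comparison of cell types describes the sorted populations. Among the named genes, macrophage and myeloid genes were the most TAM-enriched. Csf1r, the receptor for macrophage colony-stimulating factor, was 5.67 ± 0.06 (SE) log2 units higher in TAMs than in tumor cells. Itgam, which encodes the CD11b integrin chain, was 5.59 ± 0.07 higher, and Laptm5, a lysosomal membrane protein of blood cells, was 5.56 ± 0.07 higher. The inflammatory genes Cxcl2, a neutrophil-attracting chemokine, and Il1b, which encodes interleukin 1 beta, were 6.41 ± 0.07 and 6.29 ± 0.08 higher. Clec5a, Sla, F13a1, Sirpb1a and Gpr65 were 5.48 to 5.79 higher. On the tumor cell side, Il24, a cytokine of the interleukin 10 family, was lower in TAMs by a difference of -4.001 ± 0.14 and Gja1, which encodes the gap junction protein connexin 43, by -2.84 ± 0.07. Tnfrsf10b, a death receptor for TRAIL, differed by -3.46 ± 0.15 and Rbpms2, an RNA-binding protein, by -3.42 ± 0.07. B9d1, Samd4, Epha4, Mgst2, Fkbp9 and Smad5 differed by -2.75 to -2.08. All 20 of these genes passed the test, with limma adjusted p from 3.21e-10 to 1.50e-06. They are the extremes among genes that the authors had picked for genotype differences, not among all genes. In the dimmer cell type Clec5a, Sla, Il24 and Epha4 lay below the table median of 4.19 on each array, and Il1b, Gpr65, Tnfrsf10b, Samd4 and Mgst2 on some, so these differences are against a level near background and are no exact sizes.

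The TAM comparison asks how loss of integrin beta3 in the macrophage lineage alters the CD206hi TAMs of the tumor. The named gene that passed was Mid1, a microtubule-associated ubiquitin ligase, which measured 7.63 ± 0.03 (SD, n = 3) on the log2 scale in b3KOM TAMs and 6.66 ± 0.08 (SD, n = 3) in WT TAMs. Its log2 difference was 0.96 ± 0.08 (SE), or 1.95-fold, with a limma adjusted p of 0.0156.

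Genes with higher values in b3KOM TAMs included Sox4, a transcription factor of the SRY-box family, with a log2 difference of 0.64 ± 0.09 (SE) and an adjusted p of 0.0809. Rbpms2 differed by 0.62 ± 0.09 at an adjusted p of 0.0993. Ctla2a, an inhibitor of cathepsin-type cysteine proteases, differed by 0.70 ± 0.12. Zfp341, Phf16 (now Jade3), Tceal1 and Tnfrsf10b differed by 0.60 to 0.66. None of these 7 genes passed, and their adjusted p ran from 0.0809 to 0.657.

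Genes with lower values in b3KOM TAMs included Mgst2, a microsomal glutathione transferase, at 5.14 ± 0.20 (SD, n = 3) in WT and 3.93 ± 0.32 (SD, n = 3) in b3KOM, a log2 difference of -1.21 ± 0.18 (SE). Apoc1, an apolipoprotein made by lipid-handling macrophages, differed by -1.13 ± 0.26. Mgl2, a C-type lectin of alternatively activated macrophages, differed by -0.77 ± 0.23. The interferon-linked genes Nlrc5, the transcriptional activator of MHC class I genes, and Mx1, an interferon-induced antiviral GTPase, differed by -0.82 ± 0.16 and -0.59 ± 0.14. Ccdc6 differed by -0.63 ± 0.08, B9d1 by -1.004 ± 0.21, Trim13 by -0.92 ± 0.29, Mtx3 by -0.77 ± 0.18 and Taf1d by -0.68 ± 0.21. None of these 10 genes passed, with limma adjusted p from 0.0773 to 0.652. The b3KOM means of Mgst2, Mtx3 and Nlrc5 and the WT mean of Tnfrsf10b lay below the table median of 4.19, near background, so their differences are no exact sizes.

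Interferon gamma response genes were lower in b3KOM TAMs in all 9 members named through the tumor cell table, with a median log2 difference of -0.65. Gbp2, an interferon-induced GTPase, differed by -0.97 ± 0.43 (SE), Irgm2, another such GTPase, by -0.53 ± 0.22, and Cxcl9 and Cxcl10, chemokines that attract T cells, by -0.78 ± 0.47 and -0.36 ± 0.25. Of the 9 members, 1 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone or over all probesets. Camera with its preset correlation gave the list an adjusted p of 4.61e-05. The call was lost with an estimated correlation of 0.90 between members, where the adjusted p was 0.353, and fry gave an adjusted p of 0.365. The list's level varied between arrays of 1 genotype, from 7.50 to 8.66 in b3KOM and from 8.05 to 8.99 in WT, and without WT replicate 3 the median difference was -0.37 and the camera adjusted p 0.0674. The other lists gave no call in TAMs, and 0 of their members passed adjusted over the list alone. MHC class II genes had a median difference of -0.13 (camera adjusted p 0.115), macrophage markers 0.01 and chemokines -0.10.

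Of 20246 probesets, limma called 3 between TAMs of the genotypes. They were Mid1 and 2 without a name here, probeset 10389717 with a log2 difference of 1.93 and probeset 10340065 with -2.40. Both unnamed ones were singled out after their values were seen. Probeset 10340065 was the only call lower in b3KOM, and with the stricter filter 0 calls were lower. Its ID lies below the lowest named one, among 6656 probesets of which none is named, so it may not stand for a gene. At an unadjusted p under 0.05 there were 1300 probesets, against 1012 that chance would give. The fit shares 1 spread between the cell types, while TAM arrays vary more (array weights 0.49 to 0.89, against 1.47 to 1.75 in tumor cells). P-values can thus be too small in TAMs, and 1300 shows no excess. The fit on TAM arrays alone gave 0 calls, with an adjusted p of 0.234 for Mid1, and leaving out any TAM array other than WT replicate 1 took Mid1 over the threshold, with adjusted p from 0.0581 to 0.0889. It was not called without any 1 of the 4 tumor cell arrays either, where 0 probesets were called higher.

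**Figure D1:**
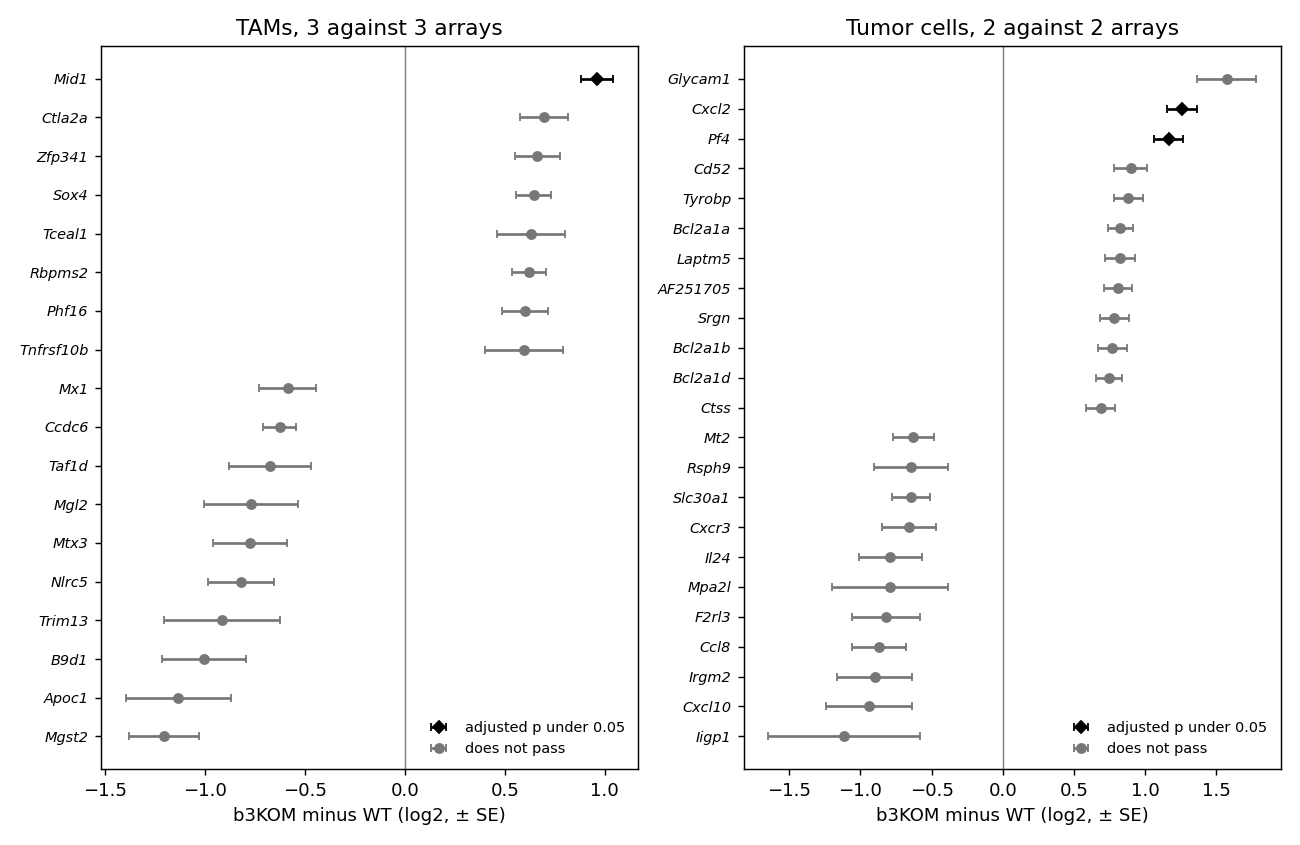
Log2 difference (b3KOM minus WT, horizontal axis) of genes named by the fixed rule, with bars of 1 SE from the limma fit, in TAMs (3 against 3 arrays) and in tumor cells (2 against 2 arrays). Diamonds are genes with an adjusted p under 0.05, which are Mid1 in TAMs and Cxcl2 and Pf4 in tumor cells, and circles are genes that did not pass.

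The tumor cell comparison asks whether the same injected cells express other genes in a b3KOM host, whose macrophages lack the integrin while the tumor cells do not carry the deletion. The genes that passed were the chemokines Cxcl2 and Pf4. Cxcl2 rose from 4.62 ± 0.05 (SD, n = 2) in cells from WT hosts to 5.88 ± 0.15 (SD, n = 2) in cells from b3KOM hosts, a log2 difference of 1.26 ± 0.11 (SE) with a limma adjusted p of 0.0218. Pf4, the platelet factor 4 chemokine that macrophages also make, rose from 7.16 ± 0.11 (SD, n = 2) to 8.32 ± 0.07 (SD, n = 2), a difference of 1.17 ± 0.10 (SE) with the same adjusted p of 0.0218. Both are strongly TAM-enriched genes, by 6.41 and 4.09 log2 units.

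Further myeloid genes had higher values in tumor cells from b3KOM hosts. Tyrobp, the DAP12 signaling adaptor of myeloid receptors, differed by 0.88 ± 0.10 (SE) at an adjusted p of 0.0995. Laptm5 differed by 0.82 ± 0.10, Cd52, a small surface glycoprotein of leukocytes, by 0.90 ± 0.12, Srgn, the granule proteoglycan serglycin, by 0.78 ± 0.10, and Ctss, the antigen-processing protease cathepsin S, by 0.69 ± 0.10. The anti-apoptotic Bcl-2 relatives Bcl2a1a, Bcl2a1b and Bcl2a1d differed by 0.74 to 0.82, and their probesets may share signal because the copies are nearly identical. AF251705 differed by 0.81 ± 0.10. Glycam1, a mucin-like gene of the lactating mammary gland and of lymph node vessels, differed by 1.57 ± 0.21. Other than Cxcl2 and Pf4, these 10 genes did not pass, with adjusted p from 0.0710 to 0.167.

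All 14 named macrophage markers were higher in tumor cells from b3KOM hosts, with a median log2 difference of 0.64. Examples are Fcer1g, an Fc receptor chain, at 0.63 ± 0.10 (SE), Cd68 at 0.66 ± 0.11, Apoe at 0.68 ± 0.11 and Csf1r at 0.45 ± 0.10. All 6 named MHC class II presentation genes were higher too, with a median of 1.004. H2-Ab1 and H2-Aa, chains of the class II molecule, differed by 1.20 ± 0.22 and 0.96 ± 0.18, and Cd74, the invariant chain, by 1.04 ± 0.20. Adjusted over the list alone, 14 of 14 macrophage markers and 6 of 6 MHC class II genes passed, and over all probesets 0 did. The authors chose these members on these arrays, so the counts are not independent evidence of direction.

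Interferon gamma response genes went the opposite way. All 9 members named through the tumor cell table had lower values in tumor cells from b3KOM hosts, with a median log2 difference of -0.90, and the 10th, Nlrc5, was not above background there (2.92 and 2.64 in cells from WT and b3KOM hosts). Iigp1, an interferon-induced GTPase, measured 7.33 ± 0.09 (SD, n = 2) and 6.22 ± 0.04 (SD, n = 2) in cells from WT and b3KOM hosts. Irgm2 differed by -0.90 ± 0.27 (SE), Cxcl10 by -0.94 ± 0.30, Mpa2l (now Gbp6) by -0.79 ± 0.41 and Cd274, which encodes the checkpoint ligand PD-L1, by -0.53 ± 0.22. Cxcr3, the receptor of Cxcl9 and Cxcl10, differed by -0.66 ± 0.19. Ccl8, a monocyte-attracting chemokine that is TAM-enriched by 4.23 log2 units, differed by -0.87 ± 0.19. Further genes in this direction were Slc30a1, a zinc exporter, at -0.65 ± 0.14, Mt2, a metallothionein, at -0.63 ± 0.14, Il24 at -0.79 ± 0.22, F2rl3, the thrombin receptor PAR4, at -0.82 ± 0.24, and Rsph9 at -0.64 ± 0.26. None of the lower genes passed, with limma adjusted p from 0.578 to 1. The b3KOM means of F2rl3, Rsph9 and Mpa2l and the WT mean of Glycam1 lay below the table median, so their differences are no exact sizes. Adjusted over the list alone, 0 of 9 interferon gamma members passed in the fit that shares its spread with the TAM arrays, where these genes vary most, and 9 of 9 in the fit on tumor cell arrays alone. These members too were chosen on these arrays, so the counts are not independent evidence. The chemokine list was split, with 2 of 5 members higher (Cxcl2 and Pf4) and 3 lower (Cxcl9, Cxcl10 and Ccl8).

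Of 20246 probesets, limma called Cxcl2 and Pf4, and 503 had an unadjusted p under 0.05, against 1012 that chance would give. The spread is shared with the more variable TAM arrays, so p-values can be too large here, and 503 shows no lack of differences. With no filter, on tumor cell arrays alone, or without any 1 tumor cell array both calls were lost, with adjusted p for Cxcl2 of 0.0561, 0.225 and 0.199 to 0.309. Without 1 TAM array there were 0 calls for 4 of the 6 arrays, 1 without WT TAM replicate 2, which was neither gene, and both genes without b3KOM TAM replicate 3.

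**Figure D2:**
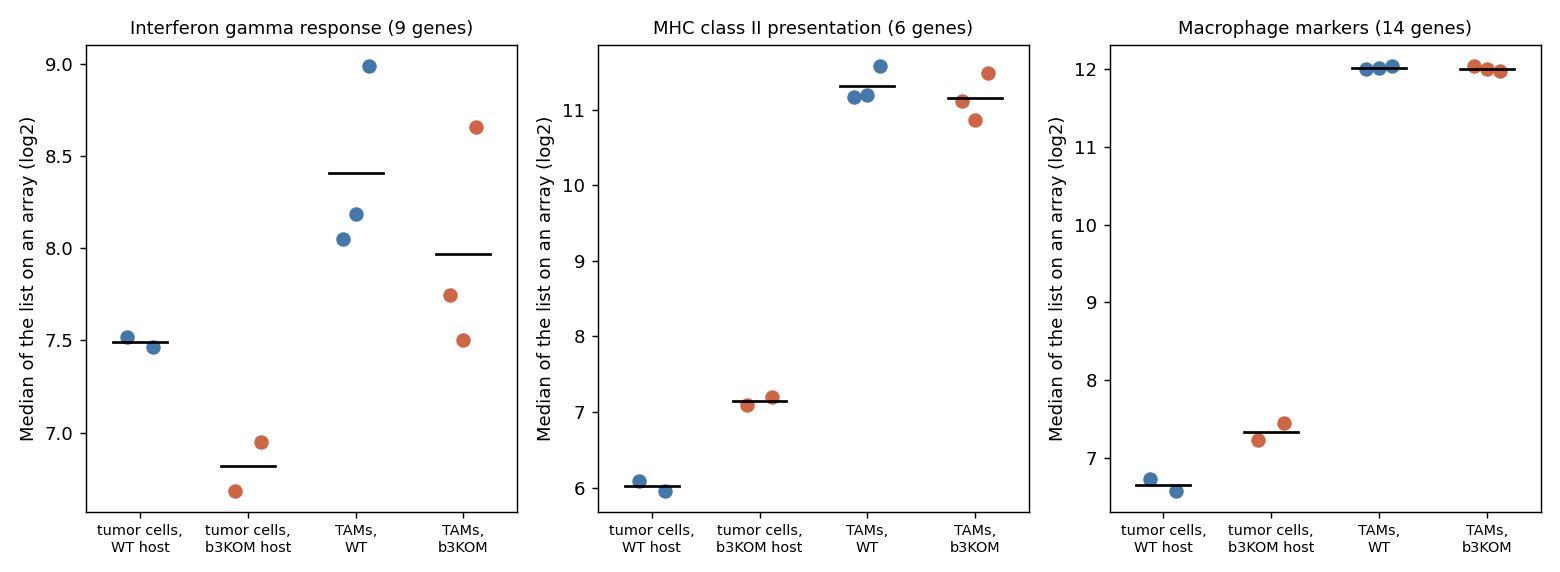
Each point is an array, and its height is the median log2 value of the named members of a list (9 interferon gamma response, 6 MHC class II and 14 macrophage genes), with a black line at the group mean. In tumor cells the list medians of the host genotypes do not overlap, with interferon gamma at 7.47 to 7.52 in WT and 6.69 to 6.95 in b3KOM. The TAM groups overlap in all 3 lists. The authors chose these members on the tumor cell arrays, so the separation there is no independent evidence. It cannot be set against the overlap in TAMs.

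The higher myeloid values in tumor cells extended beyond the named genes. Of the 337 TAM-enriched probesets, 83.7% were higher in tumor cells from b3KOM hosts, with a median log2 difference of 0.24. The median of the 337 was 4.30 and 4.46 on the b3KOM tumor cell arrays and 4.17 and 4.21 on the WT ones. Camera with an estimated correlation gave this shift a p of 0.000562. Among the 297 TAM-enriched probesets that the authors' deposited table does not list, 81.8% were higher, with a median of 0.20 and a camera p of 0.00157. The median level of these 297 was 4.12 and 4.21 on the b3KOM tumor cell arrays and 4.01 and 4.07 on the WT ones. That is near the table median of 4.19. The correlation was estimated over TAM and tumor cell arrays together. These p-values thus measure the spread between 2 tumor cell arrays per host poorly. The shift grew with TAM enrichment, from a median of 0.16 in probesets 4 to 5 log2 units brighter in TAMs (n = 210) to 0.38 in those over 5 (n = 127). Both groups include probesets that the authors chose on these arrays, so part of the growth may come from that choice. The growth was not computed for unlisted probesets alone. In the TAMs themselves the 337 probesets had a median difference of -0.03 (p of 0.508).

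**Figure D3:**
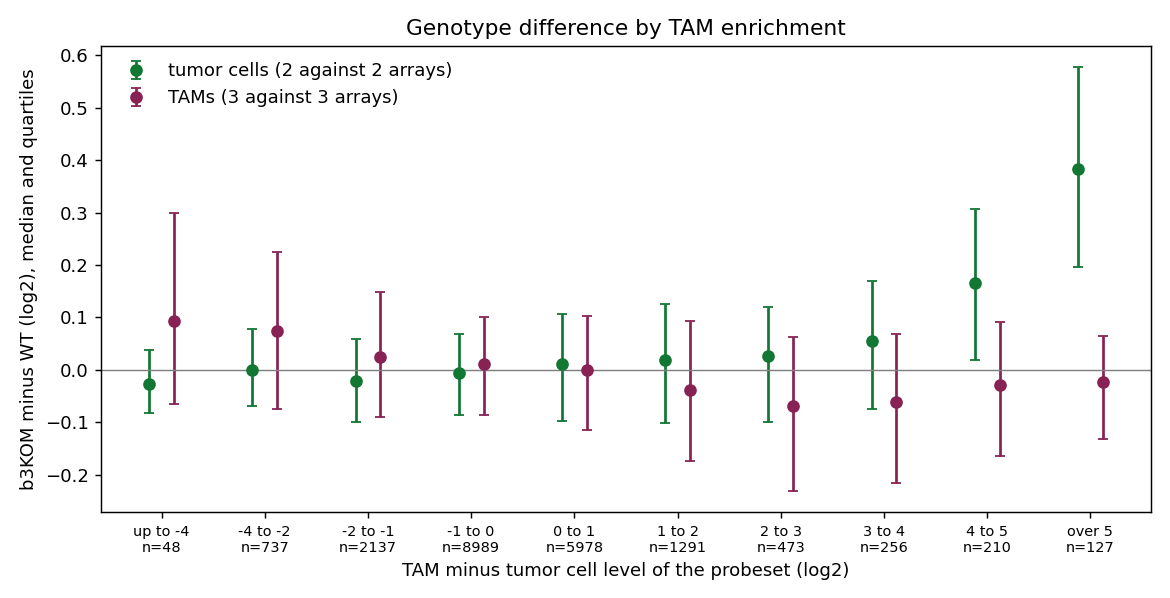
Genotype difference (b3KOM minus WT, log2, vertical axis) of tested probesets grouped by how much brighter they are in TAMs than in tumor cells (horizontal axis, log2, number of probesets under each group). Points are medians and bars run from the lower to the upper quartile. In tumor cells the median reached 0.38 in the most TAM-enriched group, while in TAMs it was -0.02 there. The groups include probesets that the authors chose on the tumor cell arrays, which may add to the rise.

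Whether the genotype acts differently in the cell types was tested by the interaction. No single probeset passed in limma, with 736 at an unadjusted p under 0.05 and 11 calls when an intensity trend and robust fitting were used. Among the named genes, the myeloid genes above had the smallest interaction p. The authors chose every named gene for a genotype difference in a cell type on these arrays, which enlarges its interaction. Zfp248 was chosen in both cell types, in opposite directions. The values of named genes below are thus no independent evidence that the genotype acts differently. Cxcl2 had a genotype difference of -0.04 in TAMs and 1.26 in tumor cells, an interaction of -1.30 ± 0.14 (SE) with an adjusted p of 0.186. Pf4 had an interaction of -1.14 ± 0.13 with the same adjusted p, followed by Tyrobp at -0.92 ± 0.13, AF251705 at -0.87 ± 0.13 and Bcl2a1a at -0.85 ± 0.11. In the other direction, Mid1 had an interaction of 0.80 ± 0.13, Zfp248 of 1.002 ± 0.17, Hspa1l, a heat shock protein, of 0.70 ± 0.18, Rbpms2 of 0.61 ± 0.14 and Adk, adenosine kinase, of 0.59 ± 0.14, with adjusted p from 0.359 to 0.975. Zfp248 and Hspa1l lay below the table median in TAMs of both genotypes.

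Across the 20246 probesets the genotype differences in TAMs and in tumor cells correlated with Pearson's r of 0.09 and Spearman's rho of 0.05, a description across genes, which are not independent replicates. Of the tested genes in the authors' deposited TAM table, 40 of 81 had the table's direction in tumor cells, and of those in the tumor cell table, 49 of 92 had it in TAMs, with fry p of 0.927 and 0.664. In their own cell type all 122 and all 130 rows had the direction of the deposited tables, of which 76 of 81 and 76 of 92 tested had an unadjusted p under 0.05 and 1 (Mid1) and 2 (Cxcl2 and Pf4) passed after adjustment. The tables were chosen on these arrays, so this overlap is not independent evidence. In the authors' deposited tables, small RNAs and the other kinds of genes the naming rule leaves out aside, the largest log2 fold changes of WT against b3KOM were 1.22 for Mgst2 and -0.87 for Mid1 in TAMs, and 1.11 for Iigp1 and -1.52 for Glycam1 in tumor cells. Hmox1, the haem-degrading enzyme, stood at -1.37 in that table, and St6galnac1 and Ubd, an interferon-inducible ubiquitin-like gene, at 0.91 and 0.97.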

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

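The tests of TAM RNA in tumor cells and of tumor cell RNA in TAMs, the share it would need included, were chosen only after the result was seen. The TAM-enriched probesets had unlike genotype differences on the TAM and tumor cell arrays. The median of TAM difference minus tumor cell difference was -0.29 on the log2 scale. A camera test of that difference with an estimated correlation gave p of 0.00201. The correlation was again estimated over both cell types, and some of these probesets were chosen by the authors on the tumor cell arrays. TAM RNA in the tumor cell samples, weighed below, would give such a gap too. No group of arrays was large enough for a test of a stray sample, but WT TAM replicate 3 had the lowest correlations with the other TAM arrays (0.981 to 0.983, against 0.983 to 0.985 among the others) and the lowest array weight (0.495).

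The pattern is that TAM-enriched transcripts were higher in sorted tumor cells from b3KOM hosts, among them Cxcl2, Pf4, MHC class II genes and macrophage markers. Equally bright probesets that are not TAM-enriched had a median difference of -0.0103 (bootstrap interval -0.0315 to 0.0103, over probesets and not arrays). In the deposited values the shift was thus not shared by probesets of that brightness. Quantile normalization holds such medians near 0, and that of all tested probesets was 7.5e-06 in tumor cells. The comparison could hardly have come out otherwise, so it says little on array scaling. RNA of TAMs in the sorted tumor cells may be the source, because 81.8% of the TAM-enriched probesets that the authors did not list were also higher, though sorting on the tumor cells' green fluorescence would be meant to remove TAMs, and admixture leaves Ccl8 unaccounted for, which is TAM-enriched yet lower (implied share -3.28%, against 4.88% for Pf4 and 4.94% for H2-Ab1, all chosen by the authors on these arrays). The unlisted probesets need an added TAM share of 0.477%, the macrophage markers 1.25% and the MHC class II genes 2.74%. The authors chose those markers and class II genes on these arrays and the unlisted probesets are the rest, so the gap to 0.477% may come from that choice. The ratio of 2.20 between class II genes and markers had an exact permutation p of 0.148. So 1 kind of admixed macrophage and several kinds cannot be told apart with 6 and 13 genes. More macrophages in tumors of b3KOM hosts, more uptake of tumor material by them, or expression by the tumor cells stay open and untested.

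The second pattern is that interferon gamma response genes (Iigp1, Irgm2, Cxcl10, Gbp2) were lower in tumor cells from b3KOM hosts. Less TAM RNA in those samples is argued against, since the TAM-enriched probesets had a median difference of 0.237, the opposite direction. T cell RNA cannot be told apart, because 0 members of the T cell marker list have a named probeset here, though the sort for tumor cells would be meant to remove T cells. A lower interferon gamma response in the TAMs of the same hosts has the matching direction in 9 of 9 genes, with a camera p of 1.15e-05 under the preset correlation, yet the p is 0.163 with the estimated one, so it stays open. A weaker interferon gamma signal in b3KOM tumors is a hypothesis that these data could carry no further.

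The third pattern is that few probesets passed between TAMs of the genotypes. The 6 TAM arrays split 3 against 3 in 10 ways, too few for a share under 0.05, and the real split gave 3 calls against at most 1 in another. More tumor cell RNA in the WT TAM samples is argued against for Mid1 and the other probeset called higher in b3KOM, since WT samples would need to hold at least 71.1% of it, while tumor cell-enriched probesets reached at most 6.21% of their tumor cell level on a TAM array. For the lower probeset 10340065 and for genes that did not pass, tumor cell RNA in the sorted TAMs cannot be told apart. That 3 of 3 called probesets were brighter in TAMs does not decide it for a lower one. After the trend with the cell type difference was removed there were 9 calls, the 3 among them. Of the tumor cell-enriched probesets, 62.5% were higher in b3KOM TAMs (camera p of 0.598 with an estimated correlation). That share was 45.8% without b3KOM TAM replicate 3, 50.0% without WT TAM replicate 3 and 87.5% without WT TAM replicate 2. Mid1 crosses the boundary of the pseudoautosomal region in laboratory mice, and the labels used here give neither the strain nor the sex of the hosts, so this was not tested. For the difference between TAMs and tumor cells, 100 splits of the 10 arrays were drawn, the real one among them. The real split gave 13664 calls in a fit of 2 groups, and the highest count in another was 51. The other splits mix the cell types, which widens the spread within groups and holds their counts down. As 1 of 100 drawn splits reached the real count, chance is unlikely but not excluded.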

How the results depend on the processing

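Alternatives that take only probesets from the ID range of named genes, and all those of the TAM-enriched shift and of single gene lists, were chosen after seeing the data. Calls between TAMs moved from 3 to 8 with the stricter filter, 9 with trend and robust fitting, 7 in the named ID range, 0 with TAM arrays alone, 16 at an adjusted p under 0.1 and 313 at an unadjusted p under 0.05 with 1.5-fold change. Such counts can hold copies, since 701 probesets were identical to another on all arrays. Among the 16, probesets 10415081, 10520121, 10578405 and 10586076 gave the same values. Calls in tumor cells moved from 2 to 0 with no filter, 17 with trend and robust fitting, 30 with array weights, 10 in the named ID range, 0 with tumor cell arrays alone, 5 at an adjusted p under 0.1 and 182 at an unadjusted p with 1.5-fold change. Interaction calls moved from 0 to 11 with trend and robust fitting and 382 at an unadjusted p with 1.5-fold change, and the cell type count from 13383 to 8878 under that last criterion. Leaving out 1 array at a time gave 0 to 5 calls in TAMs, 0 to 2 in tumor cells, 0 to 0 for the interaction and 12083 to 13282 between cell types, with the lone array of a group assumed to vary like the others. Gene lists called in TAMs went from 1 to 0 with an estimated correlation, 0 with fry, 2 by ranks (the interferon gamma and MHC class II lists) and 0 to 3 without 1 array, with 0 without WT TAM replicate 3 and 3 without b3KOM TAM replicate 3. The median of the interferon gamma list in TAMs ran from -1.03 to -0.36 without 1 array, and was -0.37 without WT replicate 3, where the call ended. The correlation of genotype effects moved from 0.0882 to 0.0474 with no filter and 0.104 with the stricter filter, and ran from 0.0512 to 0.0941 without 1 array. Of the authors' tables, adjusted calls went from 1 to 0 in TAMs and from 2 to 0 in tumor cells with 1 cell type alone. The TAM-enriched shift in tumor cells kept its direction and its side of the threshold under every alternative run, with medians of 0.20 to 0.28 without 1 array. Without 1 array the tumor cell medians ran from -0.96 to -0.75 for interferon gamma, 0.95 to 1.04 for MHC class II, 0.54 to 0.71 for macrophage markers and -0.61 to -0.54 for chemokines. Among named genes, differences near 0 in TAMs turned sign without 1 array, H2-Ab1 (-0.294 to 0.00643) and Ccl8 (-0.208 to 0.0361, and 0.00358) without WT replicate 3, Ccl8 also without b3KOM replicate 2, and Cxcl2 (-0.0701 to 0.0113) without b3KOM replicate 3. No other named gene changed direction, 14 named genes passed in tumor cells only under an alternative, and 5 did so for the interaction. The fits on 1 cell type alone have fewer arrays, and the causes of the other moves were not tested. Not run were the mean of all probesets of a gene, every setting for Itgb3, and the gene list tests in tumor cells and for the interaction, since names were lacking or chosen on these arrays, nor was a replicate block, since the titles share no numbers. Signal near background limits genes such as Mx1, Nlrc5 and Ccr2 in tumor cells, whose values lie below the table's median.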

Other observations

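The test of host DNA near Itgb3 was chosen only after the result was seen. Several smaller gene lists had too few named members for a test. In tumor cells from b3KOM hosts, Hmox1 had a log2 difference of 1.37 ± 0.21 (SE), Arg1, the arginine-degrading enzyme of alternatively activated macrophages, of 0.92 ± 0.20 and Il1b of 0.76 ± 0.13. The monocyte markers Ccr2, a chemokine receptor, and F13a1, a coagulation factor subunit, differed by 0.70 ± 0.22 and 0.50 ± 0.15. All 5 are strongly TAM-enriched, and none passed, with limma adjusted p from 0.194 to 1. In TAMs the same genes differed by -0.16 (Il1b) to 0.37 (Ccr2), and Arg1 by 0.08 ± 0.16. Glycam1, in contrast, was not a TAM gene, at 3.34 ± 0.16 (SD, n = 3) in WT TAMs. The metal-handling genes Mt2 and Slc30a1 both had lower values in tumor cells from b3KOM hosts, and Mt2 differed by -0.11 ± 0.12 (SE) in TAMs.

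Genes chosen here after their values were seen are given as values that weigh on no explanation. Tcra, the T cell receptor alpha gene, measured 3.01 ± 0.07 (SD, n = 2) in tumor cells from WT hosts and 2.53 ± 0.05 (SD, n = 2) from b3KOM hosts, below the filter and so not tested. Gimap1, a GTPase of lymphocytes, measured 3.96 ± 0.06 and 3.46 ± 0.05 there. In TAMs, Trex1, a DNA exonuclease that limits interferon induction, differed by -0.42 ± 0.12 (SE), on the same side as Nlrc5 and Mx1, with an adjusted p of 0.591.

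A hypothesis was that genes of the authors' TAM table may differ because of host DNA carried along with the floxed Itgb3 gene. Of the 118 matched genes, 11 lie on the chromosome of Itgb3, which is 1.27 times the share of RefSeq protein-coding genes there (95% interval 0.646 to 2.19, exact binomial p of 0.377). The table is too short to exclude an excess, and none was detected.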
